A study of Homo sapiens with 7 samples.

How the data were processed

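The values used were the probe set intensities deposited by the authors, 1 table of 54675 probe sets for each of 7 arrays. Per the labels, 5 µg of total RNA per sample was labelled for the array, and the algorithm that made the intensity values is not given in the sources used here. They are on a linear scale and were not brought to a common level. All 7 columns belong to this study and were used, with 0 columns from other samples.

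The choices in this paragraph were fixed before the data were examined. Values were taken as log2 of the deposited intensities without rescaling. Values below a floor of 21.35, the pooled median, were set to the floor, so a difference with an array at the floor is a lower bound and is given as at least that many fold. Probe sets were assigned to genes with the annotation table of the array, and symbols were brought up to date with a gene table of assembly GRCh38.p14, which was used for names only. Of the probe sets, 41097 listed 1 gene, 1801 listed several and 11777 were not listed. A gene is represented by its single-gene probe set with the highest mean, which gave 19775 genes, of which 14973 reached the floor on any array. A gene counted as changed at a difference of at least 1 log2 unit (2-fold). There was 1 array per condition, so no test was made and each array was compared as such: 6 heated arrays against the control, and 44 °C against 42 °C at each of 3 times.

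Genes named were those with the 6 largest rises and 4 largest falls in each of the 6 comparisons with the control, and the 5 largest each way in each of the 3 comparisons between temperatures. These came from genes past 1 log2 unit whose higher value was at least 4 times the floor and whose other probe sets above the floor all had the same sign. Up to 4 members per gene list with the largest difference of at least 1 log2 unit were added. So were 19 genes fixed in advance, of which 16 had a value and HSPA1A, HSPA1B and HSF2 had no single-gene probe set. The rule named 132 genes. EGR3, FOSL1, IER3, KLF4, KLF6, PPP1R15A, GADD45A, NFKBIA, ZFP36, IL6, CCL20, LIF, CDH2, MMP9, DNAJA4, TXNIP, ARRDC3 and ARRDC4 fell outside it and were named after their values were seen.

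The 31 gene lists were also fixed in advance. They cover the HSP70 and HSP110 family, HSP40 cochaperones, HSP90 and its cochaperones, small heat shock proteins, mitochondrial chaperones, the TRiC chaperonin, the ER unfolded protein response, the ATF4 integrated stress response, immediate early genes and p53 targets. Others are the pro-apoptotic BCL2 family, the anti-apoptotic BCL2 family with IAPs, NF-kB inflammatory genes, NRF2 oxidative stress genes, metallothioneins, proteasome subunits, G1/S and DNA replication, G2/M and mitosis, ribosomal proteins, ribosome biogenesis and oxidative phosphorylation. The rest are cholesterol synthesis and uptake, hypoxia and glycolysis, splicing factors and CLK kinases, basal squamous keratins and adhesion, squamous differentiation, invasion and mesenchymal genes, the interferon response, and fibroblast, leukocyte and endothelial markers.

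The choices in this paragraph were made after seeing the data. The arrays differed in level, so genes are said to have risen or fallen only if they passed 2-fold under all 3 scalings (as deposited, quantile normalization, median shift over the 20902 probe sets at or above the floor on all arrays). This rule is stricter for changes that go against the shift of the array. At 44 °C against 42 °C, 12 h it left 263 higher genes, as many as deposited, against 729 after quantile normalization. Counts are also given among bright genes, whose higher value is at least 4 times the floor. A list is described by its excess, the list median minus the median of 10000 random lists matched in 20 intensity bins, and by the percentile of its median among them, which is a description and not a p-value. The plan had worded the list result as the plain median, and the excess was taken because medians followed the array level. Between scalings the plain median of 75 called list results changed sign in 11 cases under quantile normalization, 12 under the median shift, 4 with the mean of probe sets and 1 without a floor. A count of genes past 4-fold among bright genes was computed and dropped.

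Unchanged arrays were simulated 100 times from the disagreement between probe sets of the same gene, whose standard deviation per comparison was 0.197 to 0.269 log2 units for bright and 0.563 to 0.690 for dim probe sets. They gave 404 genes past 2-fold each way on the deposited scale. On the 42 °C, 12 h array both counts were lower than this under every scaling, so this disagreement overstated the noise there. Elsewhere a lower count could follow the array level, as at 44 °C, 12 h, with 255 higher genes as deposited and 663 after quantile normalization. After quantile normalization the higher genes at 42 °C, 6 h (294) and 44 °C, 0 h (355) were also below the simulated range of 362 to 453. The lower genes there (369 and 390) lay inside it. The simulated noise was pooled over the comparisons with the control, so it may be overstated on these arrays too and is a rough guide. The code was tested on simulated data: of 50 genes each, 23 were recovered at a change of 1 log2 unit, 47 at 1.5 and 50 at 2 and 3, and 802 of 19775 unchanged genes passed. Of 200 random lists 197 lay inside the central 95%. Messenger RNA integrity was checked from the ratio of 3 prime to 5 prime control probe sets, which was 0.875 to 0.993 for GAPDH and 1.19 to 1.29 for ACTB. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.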

Results

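HSC-3 is an established human cell line from an oral squamous cell carcinoma of the tongue. Cells were held at 37 °C or heated at 42 °C or 44 °C for 90 min, and heated cells were collected at once (0 h) or after 6 or 12 h back at 37 °C. RNA from each of the 7 conditions was hybridised to 1 Affymetrix whole-genome expression array, so every difference below compares a pair of arrays and has no replicate check. The number of arrays limits the precision, and no p-values are given. Median probe set intensity was 22.4 on the control array, 18.7, 21.0 and 19.1 on the 42 °C arrays (0, 6 and 12 h) and 32.1, 19.3 and 19.2 on the 44 °C arrays. Over probe sets at or above the floor on every array, the median log2 difference from the control was -0.13, 0.24 and 0.16 at 42 °C and 0.40, -0.07 and -0.35 at 44 °C. Because of these array-wide shifts, a gene is said to have risen or fallen only if it differed by at least 2-fold as deposited, after quantile normalization and after a median shift. A change against the shift of its array had to be larger to pass. Counts under all scalings therefore do not give the balance of risen and fallen genes. The excess of a gene list is its median log2 difference minus that of 10000 random lists of similar intensity, given with its percentile among them.

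Heat at 42 °C was followed at 0 h by a rise of heat shock genes and a fall of inflammatory genes. HSPA6, a strictly inducible HSP70 chaperone, was below the floor in the control and at least 588-fold higher after heat, at 12566 intensity units. DNAJB1, the HSP40 partner of HSP70, rose 11.3-fold from 881 to 9949, and the cochaperone BAG3 rose 3.92-fold. CXCL2 and CXCL3, chemokines that attract neutrophils, fell 10.1-fold and 6.31-fold, and the cytokines TNF and IL1A fell 7.47-fold and 6.75-fold.

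Among the HSP70 and HSP110 family, 4 of 6 measured members rose (HSPA6, HSPA1L by 27.9-fold, HSPA4L by 2.56-fold and HSPH1 by 2.16-fold), and the list lay 1.31 above matched random lists (percentile 100). Of 9 HSP40 cochaperones, 3 rose: DNAJB1, DNAJB4 by 9.31-fold and DNAJB2 by 2.09-fold (excess 0.73, percentile 100). FKBP4, an HSP90 cochaperone, rose 2.77-fold, and with BAG3 made 2 of 9 risen members of the HSP90 list (excess 0.38, percentile 99.99). The 3 small heat shock proteins above the floor rose, HSPB1 6.46-fold, HSPB8 6.35-fold and CRYAB by 1.32 log2 units. The ER unfolded protein response list lay 0.48 above random lists (percentile 100), with HERPUD1 up 3.67-fold and DNAJB9 up 2.98-fold among 15 members. Of 16 NF-kB inflammatory genes, 10 fell and none rose (excess -1.60, percentile 0). Among 18 immediate early genes, 5 rose, including DUSP1 (7.86-fold), FOS (at least 6.07-fold), IER5 (3.55-fold), ATF3 (2.85-fold) and EGR3, and FOSL1, IER3 and KLF6 fell by 1.19, 1.74 and 1.65 log2 units. In the ATF4 integrated stress response list ATF3 and PPP1R15A rose and DDIT4, an inhibitor of mTOR, fell 4.17-fold. The p53 targets XPC (3.04-fold) and GADD45A, the cyclin CCNE2 (2.26-fold), the interferon response genes IFIT2 (at least 4.19-fold) and IRF1 (2.44-fold), the hypoxia gene ADM (2.98-fold) and the urokinase gene PLAU (2.54-fold) also fell. MMP3, which degrades extracellular matrix, rose by 3.46 log2 units and the splicing kinase CLK1 2.65-fold. Oxidative phosphorylation genes lay 0.10 above random lists (percentile 97.7, and 97.2 after quantile normalization). The mitotic (G2/M) list was 0.31 below random lists (percentile 0), although none of its 18 members fell by 2-fold.

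Beyond the lists, the largest rises at 42 °C, 0 h were in TENT5A, a non-canonical poly(A) polymerase (26.8-fold), COL2A1, the type II collagen chain (19.3-fold), the ribosomal protein pseudogene RPS16P5 (16.2-fold) and RPPH1, the RNA of ribonuclease P (3.91 log2 units). In all, 218 genes rose and 451 fell. As deposited, 219 genes were higher and 699 lower (23.9% higher), against 43.4% higher after quantile normalization and 40.1% after the median shift. Among bright genes, those reaching 4 times the floor, 127 rose and 249 fell. As deposited, 127 bright genes were higher and 382 lower (185 and 266 after quantile normalization, 186 and 255 after the median shift), and simulated unchanged arrays gave 119 (range 96 to 151) and 120 (range 87 to 143).

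After 6 h of recovery from 42 °C, part of the chaperone rise had gone and MMP3 stood far above the control. MMP3 (stromelysin-1) rose 19.4-fold to 1419, COL2A1 15.1-fold, and IL1RL1, the receptor of interleukin-33, at least 10.2-fold. CCNA1, a cyclin expressed mainly in the germ line, rose 6.66-fold and the small heat shock protein HSPB1 6.38-fold. HSPA6 was still at least 12.3-fold above the control at 262, against 12566 at 0 h, and DNAJB1 was at 1354. The largest falls were in LINC00868 (at least 5.38-fold), ZNF205 (at least 5.35-fold), EEF2KMT, a lysine methyltransferase of elongation factor 2 (at least 5.31-fold), and the alanine aminotransferase GPT (at least 5.01-fold). All 4 were below the floor at 6 h.

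At 6 h, 2 HSP70 family members remained above 2-fold under every scaling, HSPA6 and HSPA4L (2.99-fold), and the list excess was 0.73 (percentile 100). HSPH1, an HSP110 chaperone, was 2.33-fold above the control as deposited but did not pass under every scaling. The HSP40 list had an excess of 0.27 (percentile 97.7, and 95.2 after quantile normalization) with 1 risen member, DNAJA4 (1.39 log2 units), and the HSP90 list 0.38 (percentile 99.96) with FKBP4 (2.77-fold) and BAG3 (2.79-fold) up. HSPB8 was still 6.09-fold higher. The ER unfolded protein response list kept an excess of 0.52 (percentile 100), with DNAJC3, an ER cochaperone, up 2.87-fold. NRF2 oxidative stress genes lay 0.31 above random lists (percentile 99.9) and G1/S and DNA replication genes 0.41 below (percentile 0), with no member of either past 2-fold under every scaling. Mitotic genes were 0.19 above (percentile 99.6). NF-kB genes were 0.38 below (percentile 0.04), with IL6 up by 1.49 and CCL20 and LIF down by 1.01 and 1.27 log2 units. ATF4 integrated stress response genes lay at -0.47 (percentile 0.03), where CHAC1, an enzyme that degrades glutathione, fell at least 4.66-fold. Ribosomal protein and immediate early genes lay at -0.14 and -0.20 (percentiles 0.39 and 1.13), and both excesses were above 0 after quantile normalization, at 0.007 and 0.006.

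In total, 202 genes rose and 287 fell at 42 °C, 6 h. The deposited values gave 575 higher and 303 lower (65.5% higher), against 44.3% and 28.8% higher under the other scalings. As deposited, 387 bright genes were higher and 80 lower, the first above and the second below the simulated unchanged ranges. With 134 and 157 after quantile normalization and 110 and 195 after the median shift, the first lay inside and the second above, so this reading rests on the scaling.

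By 12 h after 42 °C the HSP70, HSP40 and HSP90 lists had no risen member, and genes of the integrated stress response stood above the control. HSPA6 was below the floor again, DNAJB1 was at 1299 and BAG3 at 1864, against 1816 in the control. Of 15 ATF4 targets, 8 rose, among them SLC7A11, the cystine transporter (3.43-fold), ATF3 (3.18-fold), CHAC1 (3.12-fold) and DDIT3, the pro-apoptotic factor CHOP (2.74-fold). That list lay 1.21 above random lists (percentile 100). HSPB1 remained 5.53-fold higher, COL2A1 3.98-fold and MMP3 3.53-fold.

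The HSP70 list had an excess of -0.12 (percentile 15.5) at 12 h, the HSP40 list 0.12 (percentile 85.3) and the HSP90 list -0.05 (percentile 22.8). The ER unfolded protein response list was still 0.24 above random lists (percentile 99.9) with no member past 2-fold. IL6 rose by 1.68 log2 units, IL1RL1 at least 4.67-fold and BAK1, a pro-apoptotic BCL2 family member, 2.37-fold. Metallothioneins, which bind zinc and copper, lay 0.31 above (percentile 99.9) with MT1M up 2.70-fold. Mitotic genes were 0.28 above (percentile 99.99), G1/S genes 0.33 below (percentile 0.01), and splicing factors and CLK kinases 0.18 below (percentile 0.73), with no member past 2-fold under every scaling. The immediate early list was 0.17 above (percentile 97.6), with ATF3 and KLF4 up, and ribosomal proteins were 0.13 below (percentile 0.17). Both lay inside the central 95% after quantile normalization, at 0.12 (percentile 94.5) and -0.02 (percentile 35.9). Other large rises were in VIPR1, a receptor of vasoactive intestinal peptide (4.76-fold), IRF2BP1 (4.75-fold), LINC02806 (at least 4.39-fold) and ARL9 (at least 4.17-fold). The largest falls were in ADAMTS13, the protease of von Willebrand factor (at least 5.17-fold), GPT (at least 5.01-fold), LINC00868 (5.00-fold) and LINC02352 (4.56-fold).

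This array was the closest to the control, with 141 genes risen and 199 fallen. As deposited, 268 were higher and 248 lower (51.9% higher, 52.3% after quantile normalization and 30.5% after the median shift). Bright genes as deposited numbered 147 higher, inside the simulated unchanged range, and 54 lower, below it, and both were below it after quantile normalization (82 and 68) and the median shift (67 and 84). Counts below that range mean that the simulated noise was too large for this array. The comparison therefore cannot tell whether it differs from an unchanged one.

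**Figure D1:**
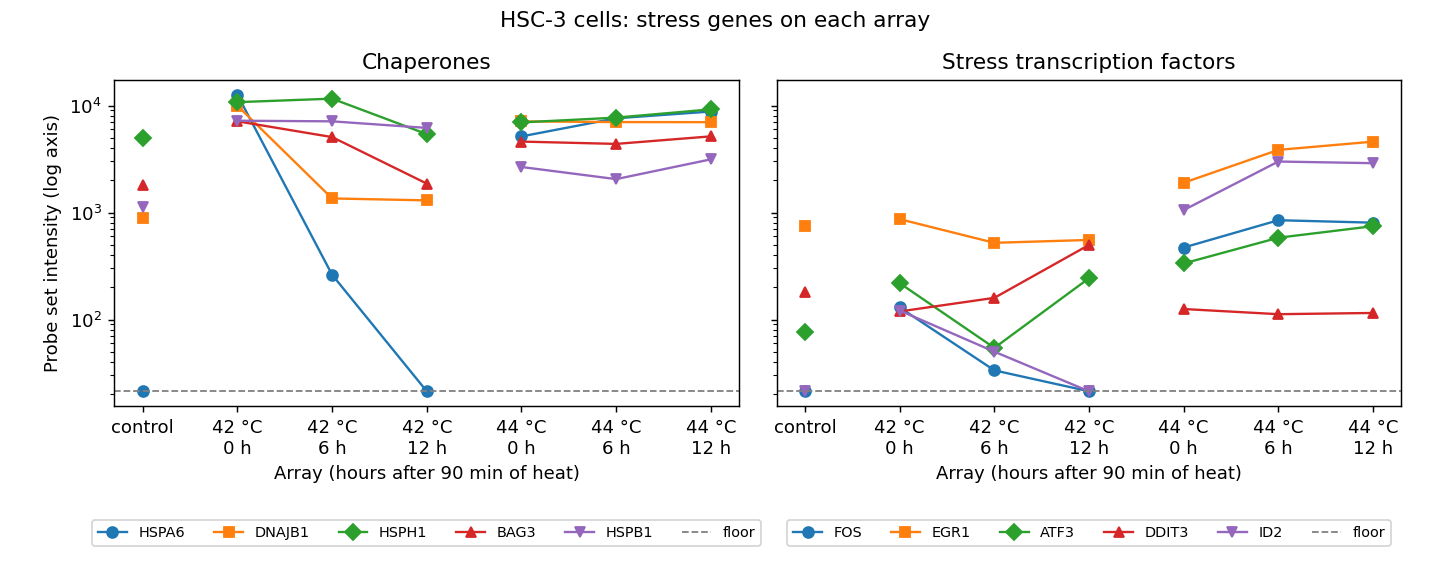
Probe set intensity (log axis) of 5 chaperone genes and 5 stress transcription factors on each of the 7 arrays, 1 point per array, with values below the floor drawn at the floor (dashed line). HSPA6 returned below the floor by 12 h after 42 °C but read 8788 at 12 h after 44 °C, and FOS read 804 there.

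Heat at 44 °C raised heat shock genes at 0 h together with immediate early genes, while 1 of 16 inflammatory genes fell. HSPA6 was at least 241-fold above the control at 5143, DNAJB1 rose 8.07-fold and DNAJB4 3.07-fold. ID2, an inhibitor of basic helix-loop-helix transcription factors, rose at least 49.4-fold. FOS, a subunit of the AP-1 transcription factor, rose at least 22.0-fold, and the Ras-related GTPase RASD1 at least 18.0-fold. TNF and IL1A differed from the control by 0.14 and 0.13 log2 units.

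Of the HSP70 family, HSPA6 and HSPA1L (4.62-fold) rose, and the list excess was 0.37 (percentile 98.7). The HSP40 list lay at 0.27 (percentile 95.8) and the HSP90 list at 0.14 (percentile 87.4), and HSPB1 was at 2664 against 1116, a difference that did not reach 2-fold under every scaling. Of 18 immediate early genes 4 rose, FOS, FOSB (at least 6.58-fold), DUSP1 (6.04-fold) and ATF3 (4.36-fold), with a list excess of 0.39 (percentile 99.9). NF-kB genes were 0.37 below random lists (percentile 1.20), with CXCL2 down 2.73-fold. The p53 target list lay 0.47 below (percentile 0.29), although PLK3 was up 5.49-fold, and the ATF4 list 0.34 below (percentile 2.29). In cholesterol synthesis, HMGCS1 (2.80-fold) and DHCR7 (2.73-fold) rose, with a list excess of 0.11 (percentile 67.3). In the invasion list, SNAI1, a repressor of E-cadherin, rose at least 6.21-fold and fibronectin (FN1) 3.09-fold, while N-cadherin (CDH2) fell. G1/S genes were 0.22 above random lists (percentile 98.7), oxidative phosphorylation genes 0.17 above (percentile 97.99) and ribosomal proteins 0.18 below (percentile 1.07), with no member of these past 2-fold under every scaling. The latter 2 lay inside the central 95% after quantile normalization, at 0.15 (percentile 97.3) and -0.03 (percentile 30.7).

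RPS16P5 (32.2-fold) and RPPH1 (28.4-fold) were among the largest rises here too. The largest falls were in VMP1, a membrane protein of autophagy (7.78-fold), COX3, a mitochondrially encoded subunit of cytochrome c oxidase (2.93-fold), KLHL23 (2.78-fold) and the probe set annotated to the MIR205 gene (2.70-fold), which does not measure the mature microRNA. Under all scalings 348 genes rose and 100 fell. As deposited, 1470 genes were higher and 101 lower (93.6% higher), against 47.7% after quantile normalization and 62.8% after the median shift, so the balance of higher and lower genes on this array rests on the scaling.

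At 6 h after 44 °C 8 of 18 immediate early genes and several chaperone genes were above the control. HSPA6 read 7596 (at least 356-fold above the control) and DNAJB1 7004 (7.95-fold). ID2 was at least 140-fold higher, FOS at least 39.7-fold, RASD1 at least 35.5-fold and TENT5C, a poly(A) polymerase, at least 16.8-fold. EGR1, an early growth response transcription factor, rose 5.15-fold from 747 to 3849, and GADD45B, a stress sensor of the growth arrest and DNA damage family, 4.54-fold. RPPH1 was 15.7-fold higher.

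The HSP70 list lay 1.43 above random lists (percentile 100), with HSPA1L (9.55-fold) and HSPA2 (5.24-fold) up beside HSPA6. Of the immediate early genes 8 rose and ZFP36, which destabilises AU-rich messenger RNAs, fell by 1.45 log2 units, with an excess of 0.94 (percentile 100). NF-kB genes lay 0.59 below (percentile 0), with CXCL2 (3.48-fold) and NFKBIA, the inhibitor of NF-kB, down. The HSP40 list at 6 h was at 0.20 (percentile 91.3), but at 0.37 (percentile 99.3) after quantile normalization, with DNAJB1 and DNAJB4 (2.06-fold) up. The HSP90 list was at 0.16 (percentile 97.1) with BAG3 (2.41-fold) up. CRYAB, a small heat shock protein also found in the eye lens, rose 7.62-fold, and the small heat shock protein list had an excess of 0.06 (percentile 98.9). The ATF4 list was 0.49 below (percentile 0.26), with ATF3 up 7.59-fold and CHAC1 (at least 4.66-fold), SLC7A11 (3.02-fold) and DDIT4 (2.30-fold) down. The p53 list was 0.33 below (percentile 2.26), with MDM2, the ubiquitin ligase of p53, down 2.53-fold and PLK3 up 3.21-fold. Oxidative phosphorylation genes lay 0.16 above (percentile 99.8), and the invasion list 0.25 above (percentile 98.1), but 0.12 (percentile 85.4) after quantile normalization, with SNAI1 (at least 3.32 log2 units) and MMP3 (2.30-fold) up. BAK1 rose 2.11-fold and IFIT2 fell 2.93-fold.

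The largest falls at 44 °C, 6 h were in COX3 (8.64-fold), the MIR205 probe set (8.34-fold), VMP1 (7.13-fold) and EEF2KMT (at least 5.31-fold). In all, 222 genes rose and 365 fell, with 226 higher and 614 lower as deposited (26.9% higher, against 48.7% and 49.0% under the other scalings). Bright genes as deposited numbered 96 higher, inside the simulated unchanged range, and 366 lower, above it. After quantile normalization (178 and 236) and the median shift (189 and 208) both were above it, and 92 rose and 197 fell under all scalings.

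At 12 h after 44 °C 7 of 18 immediate early genes and several chaperone genes were above the control. HSPA6 read 8788 (at least 412-fold above the control), ID2 2892 (at least 135-fold) and FOS 804 (at least 37.6-fold). COL2A1 rose 37.4-fold, RASD1 at least 29.2-fold, HSPA1L 18.3-fold, CRYAB 11.3-fold and the transcription factor ATF3 9.73-fold. EGR1 was 6.15-fold and GADD45B 6.76-fold above the control. The largest falls were in the MIR205 probe set (8.03-fold), NHLRC2 (7.45-fold), GEMIN4, a component of the SMN complex that assembles spliceosomal particles (6.85-fold), and the glycosyltransferase GXYLT1 (at least 6.84-fold).

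The HSP70 list was 1.78 above random lists (percentile 100), again with HSPA6, HSPA1L and HSPA2 (4.84-fold) up, and the HSP90 list 0.41 above (percentile 99.97), with BAG3 up 2.84-fold. DNAJB1 (7.93-fold) and DNAJB4 (2.01-fold) made 2 of 9 risen HSP40 cochaperones (excess 0.30, percentile 94.1). The small heat shock proteins CRYAB, HSPB8 (3.88-fold) and HSPB1 (2.81-fold) rose. Of the immediate early genes 7 rose, including FOSB (at least 12.5-fold) and DUSP1 (9.02-fold), with an excess of 1.01 (percentile 100). The invasion list was 0.50 above (percentile 99.99), with SNAI1 (at least 15.5-fold) and MMP3 (5.78-fold) up. Anti-apoptotic genes lay 0.57 below (percentile 0.83) and mitotic genes 0.35 below (percentile 0.41). No member of either fell under every scaling, and as deposited XIAP was 2.41-fold and CENPE 2.63-fold below the control. In the mitochondrial chaperone list GRPEL2, a cochaperone of mitochondrial HSP70, fell 3.02-fold, and the list had an excess of 0.23 (percentile 91.5). Oxidative phosphorylation genes lay 0.18 above (percentile 98.6, and 97.0 after quantile normalization). MDM2 (2.81-fold), CXCL2 (3.56-fold), CHAC1 (3.48-fold), SLC7A11 (3.05-fold), IFIT1 (at least 3.13-fold) and IFIT2 (at least 4.19-fold) fell. PLK3 was 2.97-fold higher in its brightest probe set, but averaging its probe sets gave -0.02 log2 units.

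Under all scalings 255 genes rose and 439 fell. As deposited, 255 were higher and 1375 lower (15.6% higher), against 53.4% after quantile normalization and 64.6% after the median shift, so the balance on this array also rests on the scaling. Bright genes as deposited numbered 106 higher and 1040 lower, against 119 and 120 on simulated unchanged arrays. They numbered 331 and 347 after quantile normalization and 379 and 278 after the median shift, and 106 rose and 280 fell under all scalings.

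**Figure D2:**
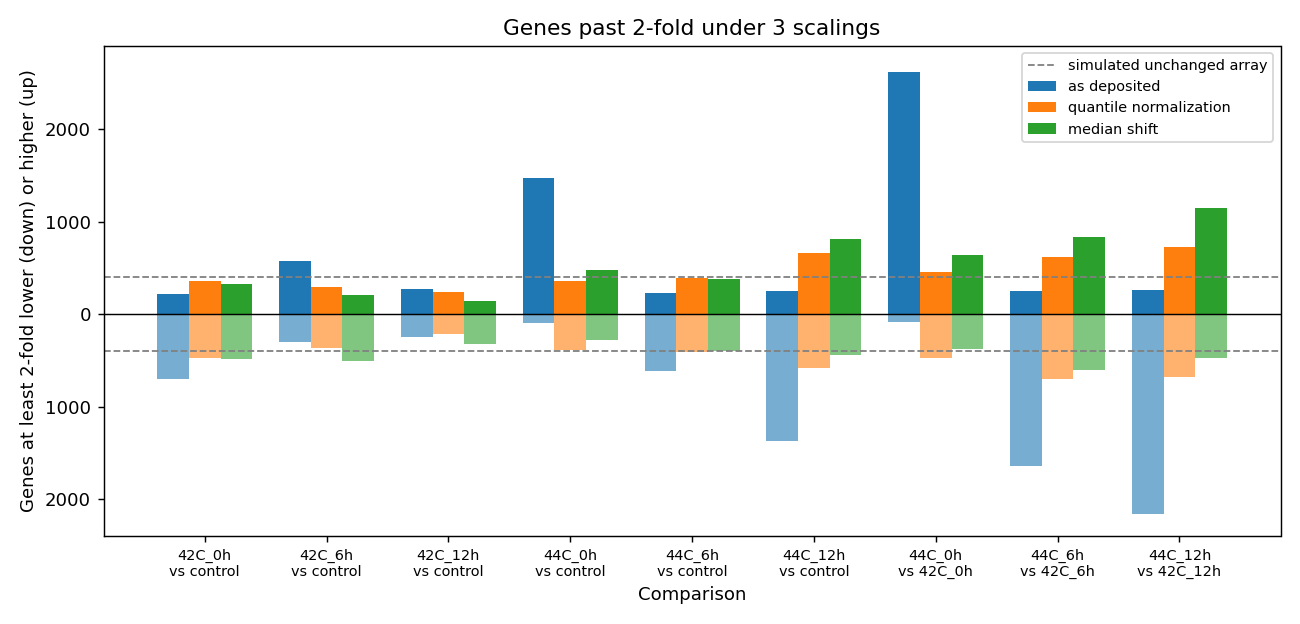
Number of genes at least 2-fold higher (bars up, dark) or lower (bars down, pale) in each of the 9 comparisons, as deposited, after quantile normalization and after a median shift. Dashed lines mark the 404 genes each way found on simulated unchanged arrays without rescaling, and the 44 °C, 0 h array had 1470 higher genes as deposited but 355 after quantile normalization.

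Set directly against 42 °C at 0 h, the 44 °C array had lower inducible chaperones and higher inflammatory genes. HSPA6 was 2.44-fold lower, DNAJB4 3.03-fold lower and HSPB1 2.71-fold lower at 44 °C. TNF was 8.23-fold, IL1A 7.38-fold, CXCL3 4.91-fold and CXCL2 3.71-fold higher. The histone gene H2AC17 was 23.2-fold higher, RASD1 at least 18.0-fold, ID2 8.69-fold and the antisense transcript NDUFV2-AS1 7.47-fold. PNLDC1, a poly(A)-specific exonuclease of the germ line, was at least 14.9-fold lower, MMP3 9.46-fold, PWWP3B at least 5.35-fold, HERPUD1 4.02-fold and COL2A1 3.68-fold lower.

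The HSP70, HSP40 and HSP90 lists were 1.29, 0.59 and 0.33 below random lists at 0 h (percentiles 0, 0.30 and 1.31). HSPA1L was 6.05-fold lower in its brightest probe set, but the mean over its probe sets was 1.04 log2 units higher. Of 16 NF-kB genes 10 were higher under every scaling (excess 1.19, percentile 100), and G1/S genes lay 0.31 above random lists (percentile 99.99). The ATF4 list lay 0.45 below (percentile 0.32), although DDIT4 was 4.48-fold higher, and ribosomal proteins 0.16 below (percentile 1.75), but -0.04 (percentile 26.6) after quantile normalization. The ADM gene, a vasodilator peptide of the hypoxia list, was 3.55-fold higher, IRF1 4.12-fold, the protease PLAU 2.98-fold and PLK1, a mitotic kinase, 3.24-fold, whereas the splicing kinase CLK1 was 2.57-fold and DNAJB9 2.63-fold lower. Under all scalings 446 genes were higher and 91 lower, against 2616 and 91 as deposited (96.6% higher, 49.0% after quantile normalization and 62.9% after the median shift).

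At 6 h 3 HSP70 genes and 8 of 18 immediate early genes were higher on the 44 °C array than on the 42 °C array, and HSPA4L, HSPB1 and HSPB8 were lower. ID2 was 59.9-fold, FOS 25.3-fold, RASD1 22.1-fold and RPPH1 14.9-fold higher, and HSPA6 was higher by 4.86 log2 units. DNAJB1 was 5.17-fold, EGR1 7.39-fold and DUSP1, a MAP kinase phosphatase, 7.45-fold higher. ZNF92, a zinc finger gene, was 10.8-fold lower, CAVIN2 at least 8.78-fold, MMP3 8.44-fold, VMP1 8.01-fold and the MIR205 probe set 7.97-fold lower.

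The HSP70 list lay 1.21 above random lists (percentile 100) with HSPA1L (5.71-fold), HSPA2 (4.69-fold) and HSPA6 higher and HSPA4L (3.09-fold) lower. Immediate early genes were 0.62 above (percentile 100, 8 higher), G1/S genes 0.42 above (percentile 100) and hypoxia and glycolysis genes 0.30 above (percentile 99.3), but 0.04 (percentile 61.4) after quantile normalization. Oxidative phosphorylation genes lay 0.14 above (percentile 97.6, and 95.8 after quantile normalization). Mitotic genes were 0.46 below (percentile 0.05) and anti-apoptotic genes 0.60 below (percentile 1.24), with no member lower under every scaling. IFIT2 (5.79-fold), IFIT1 (3.89-fold) and IFIT3 (3.26-fold), interferon-induced genes, were lower, with a list excess of -0.27 (percentile 14.96). HSPB8 (4.17-fold), HSPB1 (3.47-fold), DNAJC3 (3.50-fold), SEL1L (3.44-fold) and MDM2 (3.51-fold) were lower and CRYAB 4.96-fold, PLK3 2.63-fold and CCNE1 2.22-fold higher. Under all scalings 251 genes were higher and 603 lower, against 251 and 1646 as deposited (13.2% higher, 47.1% after quantile normalization and 57.9% after the median shift).

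At 12 h the largest gaps between the temperatures were in HSPA6 (at least 412-fold higher at 44 °C), ID2 (at least 135-fold), FOS (at least 37.6-fold), RASD1 (at least 29.2-fold) and RPPH1 (at least 19.0-fold). The ATF4 targets went the other way. CHAC1 was 10.9-fold, SLC7A11 10.5-fold, DDIT4 5.15-fold and DDIT3 4.32-fold lower at 44 °C, while ATF3 was 3.06-fold higher. Together 9 of 15 were lower and 1 higher, with an excess of -1.45 (percentile 0). The MIR205 probe set was 11.2-fold, MIGA1, a mitochondrial outer membrane protein, 9.64-fold and the zinc finger gene ZBTB41 8.24-fold lower.

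HSP70 genes lay 2.23 above random lists at 12 h (percentile 100), with HSPA1L 12.0-fold and HSPA2 7.09-fold higher, and the HSP90 list 0.40 above (percentile 99.9, and 94.6 after quantile normalization), with BAG3 2.76-fold higher. DNAJB1 was 5.38-fold higher and DNAJB14 3.41-fold lower. CRYAB (6.28-fold) and HSPB8 (3.26-fold) were higher. Immediate early genes were 0.89 above (percentile 100, 7 higher) and the invasion list 0.78 above (percentile 100), with SNAI1 at least 15.5-fold higher and the gelatinase MMP9 also higher. G1/S genes lay 0.34 above (percentile 99.4), splicing factors and CLK kinases 0.36 above (percentile 99.5) and ribosomal proteins 0.23 above (percentile 99.7), but 0.00 (percentile 51.4) after quantile normalization. Mitotic genes were 0.65 below (percentile 0) and anti-apoptotic genes 0.81 below (percentile 0.03), where XIAP and BIRC2, inhibitors of apoptosis, were 2.69-fold and 2.65-fold lower as deposited but not under every scaling. VEGFA (3.15-fold), RRM2B (3.84-fold), MDM2 (3.20-fold), IL1A (3.67-fold) and MT1M (3.29-fold) were lower, and PLK3 was 2.39-fold higher in its brightest probe set but lay at -0.12 log2 units with the probe sets averaged. Under all scalings 263 genes were higher and 468 lower, against 263 and 2162 as deposited (10.8% higher, 51.8% after quantile normalization and 70.8% after the median shift).

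**Figure D3:**
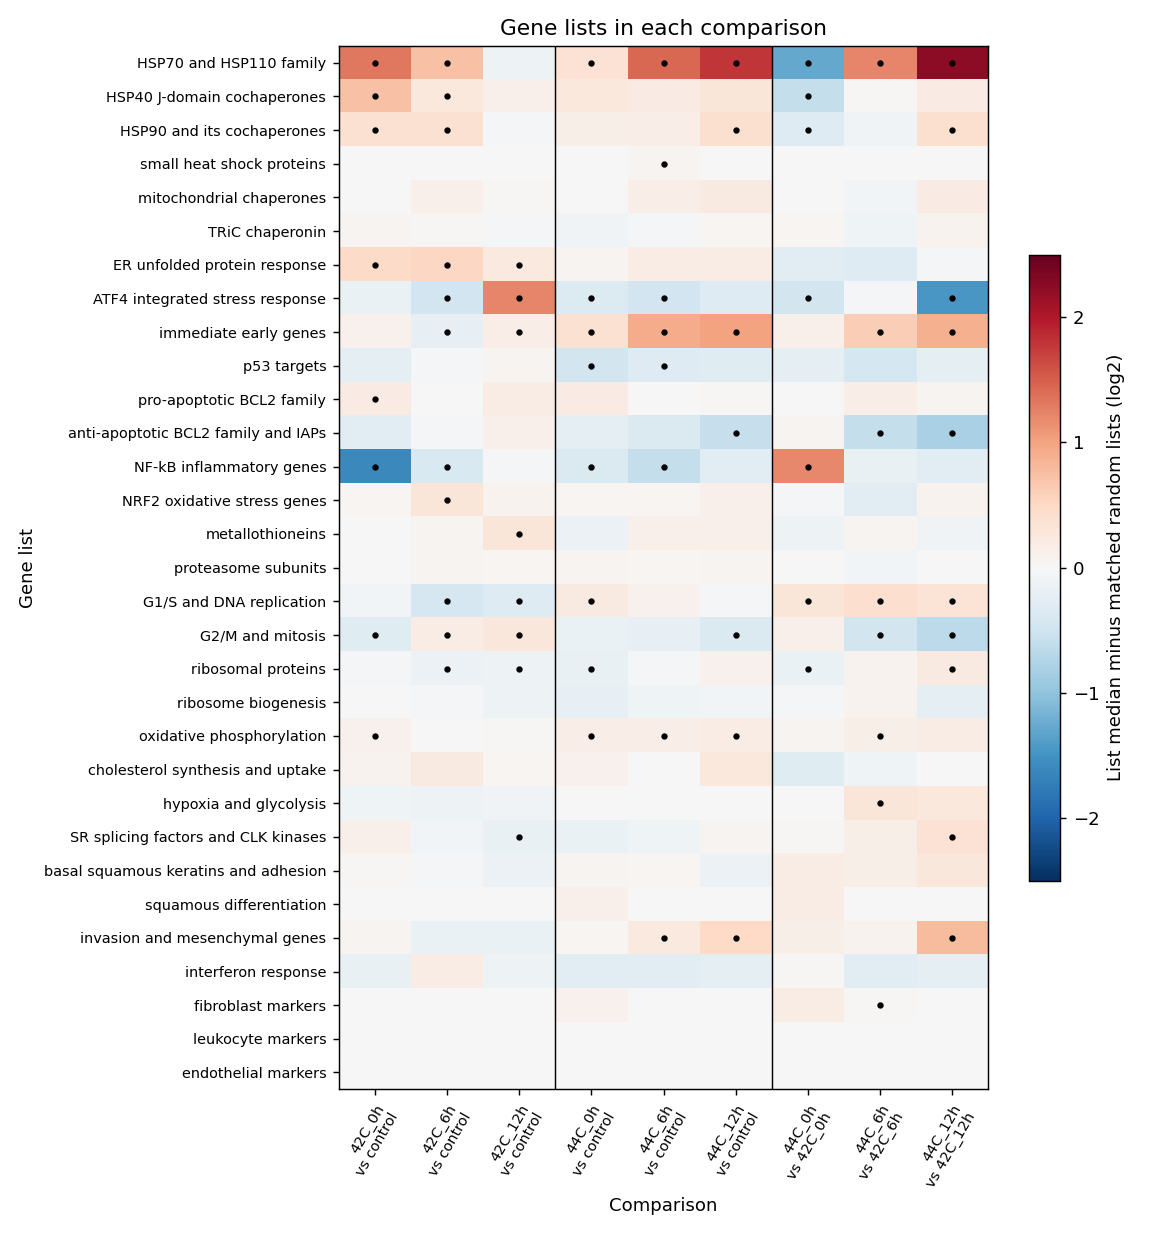
Excess of each of the 31 gene lists over matched random lists (colour, log2) in the 9 comparisons, with a dot where the list lay outside the central 95% of random lists. The HSP70 and HSP110 list ran from -1.29 (44 °C against 42 °C, 0 h) to 2.23 (44 °C against 42 °C, 12 h), and the ATF4 list from -1.45 to 1.21.

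The genes that changed at both temperatures at the same time included HSPA6, DNAJB1 and FOS at 0 h. Under all scalings, 69 genes rose at both temperatures at 0 h, 44 at 6 h and 31 at 12 h, and 38, 69 and 61 fell at both. Independent lists of these sizes would share 5.1, 3.0 and 2.4 rising and 3.0, 7.0 and 5.8 falling genes. As deposited, 116, 74 and 40 genes were higher and 55, 103 and 104 lower at both, against 21.5, 8.7 and 4.6 and 4.7, 12.4 and 22.8 for independent lists. Pairs of simulated unchanged arrays that share a control had a median of 146 genes changed the same way (range 42 to 292). This figure pools the genes higher on both and those lower on both. It therefore gives no separate figure for either direction and cannot be set against the observed higher or lower overlaps 1 by 1. Those simulated lists held 404 genes each way and the observed lists differ from that in length, so with 1 control array, which could not be split, how much of the excess comes from it stays open.

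Several groups had no gene past the threshold. No member of the TRiC chaperonin, proteasome, ribosomal protein, ribosome biogenesis or oxidative phosphorylation lists passed 2-fold under every scaling in any comparison. Excesses over the 9 comparisons ran from -0.11 to 0.09 for TRiC, from -0.07 to 0.07 for 27 proteasome subunits and from -0.24 to 0.09 for ribosome biogenesis, with none outside the central 95%. They ran from -0.18 to 0.23 for ribosomal proteins and from 0.00 to 0.18 for oxidative phosphorylation, each outside the central 95% in several comparisons. Among pro-apoptotic BCL2 genes, 0.20 above random lists at 42 °C, 0 h (percentile 99.3), BMF was at least 2.31-fold lower than the control on every heated array but 44 °C, 6 h. HMOX1, the inducible heme oxygenase, rose at least 2.73-fold at 42 °C, 0 h and at least 3.20-fold and 2.63-fold at 44 °C, 0 and 12 h. Basal squamous keratin and adhesion genes had no member past 2-fold under every scaling, with excesses from -0.16 to 0.29. Of the squamous differentiation genes KLK7, a protease of skin shedding, alone changed, falling 2.20-fold at 42 °C, 6 h, where the list excess was 0.00. The fixed genes HSF1, CDKN1A, JUN, GAPDH and ACTB stayed within 2-fold of the control on every heated array, as deposited.

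Of 8 fibroblast, 6 leukocyte and 6 endothelial markers, 6, 3 and 1 were above the floor on at least 1 array. COL1A1, a fibroblast collagen, was 2.20-fold higher at 44 °C, 6 h, and the monocyte marker CD14 at least 2.04-fold higher at 44 °C, 12 h. The excess of each of these lists against the control lay between 0.00 and 0.11. For 44 °C against 42 °C the fibroblast list lay at 0.18 (percentile 84.7) at 0 h and at 0.03 (percentile 99.3) at 6 h. At 6 h only 4 of its 8 members were above the floor, so that percentile says little.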

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

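The control probe sets on the array were looked at beside the genes, and the first 2 tests in this paragraph were chosen after the result was seen. The control probe set AFFX-M27830_5_at was 15.9-fold above the control array at 42 °C, 0 h and 42.7-fold, 38.1-fold and 35.5-fold above it at 44 °C, 0, 6 and 12 h, while AFFX-M27830_M_at was 4.79-fold, 5.93-fold, 4.79-fold and 4.24-fold above. At 42 °C they read 1.63-fold and 2.33-fold the control array at 6 h, and 0.819-fold and 1.19-fold at 12 h. AFFX-M27830_3_at, below the floor in the control, was at least 2.38-fold higher at 42 °C, 0 h and at least 2.01-fold, 1.84-fold and 2.23-fold at 44 °C. On the 42 °C, 0 h array and the 44 °C arrays the median log2 change of the hybridisation controls was at most 0.071. The array-wide shift was at most 0.40, so brighter hybridisation does not account for rises of this size. The 3 prime to 5 prime ratios of GAPDH and ACTB were at most 1.02 times those of the control array. They gave no sign of more degraded messenger RNA, but other messenger RNAs were not checked. More labelling of RNA without a poly(A) tail in general was tested with a list of small non-coding and ribosomal RNAs without RPPH1, written before its values were seen, and its lowest excess was -0.401. Of its 8 members above the floor only 2 reach 4 times the floor, so this decides nothing. Of these, the ribosomal RNA gene RNA45SN5 differed from the control by -0.35 log2 units at 42 °C, 0 h and by 1.56, 1.61 and 1.15 at 44 °C, 0, 6 and 12 h. SCARNA15 differed by 0.08, 0.52, 0.10 and 0.23 on the same 4 arrays. RPPH1, the RNA of ribonuclease P, was 3.91, 4.83, 3.98 and 3.89 log2 units above the control on these 4 arrays. The pseudogene RPS16P5 was 4.02, 5.01, 3.50 and 2.97 log2 units above it there, and 0.93 and 0.66 at 42 °C, 6 and 12 h. The heat shock gene HSPA6 was high on the same 4 arrays too, so sharing this pattern does not tell what raised RPPH1 or RPS16P5. The 3 AFFX-HUMRGE/M10098 control probe sets were 0.899-fold to 1.61-fold the control array at 42 °C, 0 h, 2.75-fold to 3.29-fold at 44 °C, 0 h, 1.29-fold to 2.24-fold at 6 h and 1.22-fold to 1.79-fold at 12 h, and since the sources used here do not say what either group of probe sets measures, the cause stays open.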

How the results depend on the processing

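Counts of genes past 2-fold were compared across settings, always in the order 42 °C at 0, 6 and 12 h and 44 °C at 0, 6 and 12 h against the control, then 44 °C against 42 °C at 0, 6 and 12 h. As deposited they were 219, 575, 268, 1470, 226, 255, 2616, 251 and 263 higher and 699, 303, 248, 101, 614, 1375, 91, 1646 and 2162 lower. In every setting below the cause was not tested.

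After quantile normalization 362, 294, 240, 355, 387, 663, 453, 622 and 729 genes were higher and 472, 369, 219, 390, 407, 578, 472, 698 and 677 lower. Genes lower at both temperatures at 0 h were 97 (55 as deposited) and higher at 12 h 80 (40). After a median shift 328, 203, 142, 480, 381, 813, 639, 836 and 1149 were higher and 489, 502, 323, 284, 397, 445, 377, 608 and 475 lower.

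Without a floor 2092, 2448, 2035, 4157, 2155, 2310, 5996, 2622 and 2906 were higher and 3319, 2893, 2886, 1412, 2973, 3641, 1265, 3693 and 4103 lower. Genes changed at both temperatures were then 1406, 1135 and 1085 higher and 761, 1216 and 1187 lower at 0, 6 and 12 h. With the floor at the pooled 75th percentile 70, 201, 55, 489, 48, 55, 939, 40 and 54 were higher and 158, 4, 8, 20, 182, 605, 43, 988 and 1284 lower, and 25, 8 and 5 were higher and 5, 0 and 3 lower at both temperatures. Lists outside the central 95% at 44 °C, 0 h were then 4 instead of 8.

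With the mean over all probe sets of a gene 139, 308, 141, 961, 142, 178, 1775, 137 and 169 were higher and 424, 139, 128, 48, 343, 786, 55, 1101 and 1329 lower, and 75, 38 and 19 were higher and 27, 46 and 51 lower at both temperatures. Lists outside the central 95% were 4 instead of 8 at 44 °C, 0 h and 14 instead of 8 at 44 °C, 6 h.

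Under all 3 scalings, a setting added after the data were seen, 218, 202, 141, 348, 222, 255, 446, 251 and 263 were higher and 451, 287, 199, 100, 365, 439, 91, 603 and 468 lower. Among bright genes as deposited, also added after the data were seen, 127, 387, 147, 907, 96, 106, 1790, 111 and 104 were higher and 382, 80, 54, 38, 366, 1040, 56, 1428 and 1884 lower.

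Few list excesses and named gene differences changed sign, whereas the plain medians of the 75 called list results did so in 11 cases under quantile normalization and 12 under the median shift. The immediate early list at 42 °C, 6 h had an excess of -0.203 as deposited, 0.006 after quantile normalization and 0.020 after the median shift, and the ribosomal protein list there -0.138 and 0.007 after quantile normalization. With the mean over probe sets, HSPA1L at 44 °C against 42 °C, 0 h went from -2.60 to 1.04 log2 units, and PLK3 went from 1.57 to -0.021 at 44 °C, 12 h against the control and from 1.26 to -0.116 against 42 °C, 12 h.

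Of 75 list results outside the central 95% as deposited, 60 stayed outside after quantile normalization, 74 after the median shift, 72 without a floor, 65 with the higher floor and 60 with the mean over probe sets. Of 486 named gene differences of at least 1 log2 unit, 383, 380, 486, 304 and 397 stayed past it in the same order.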

Other observations

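In an exploration of 22 gene families taken from gene symbols, clustered histone genes and the arrestin-domain genes around TXNIP stood out. All 22 families were written after the data were seen. Their excesses describe these same arrays and are not independent support. Messenger RNAs of clustered histone genes normally lack a poly(A) tail, but members were matched by symbol and not all need share that trait. The 28 genes lay 0.53, 0.42 and 0.74 log2 units above matched random lists at 44 °C, 0, 6 and 12 h, against 0.09, -0.13 and -0.13 at 42 °C. The 14 with a mean of at least 4 times the floor lay 0.38, 0.39 and 0.51 above at 44 °C. H2AC17 read 49.1 in the control, 535 at 44 °C, 0 h and 186 at 44 °C, 12 h. TXNIP, an inhibitor of thioredoxin, and ARRDC3 and ARRDC4 together lay 0.77, 1.60 and 1.12 above at 42 °C and -0.13, 0.36 and 0.98 at 44 °C, with TXNIP at 949 in the control and 3434 at 42 °C, 6 h.

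The 44 °C, 0 h array had more higher than lower genes and the 44 °C, 12 h array more lower genes, and all tests below were chosen after the result was seen. At 0 h the hybridisation controls changed by -0.159 against an array shift of 0.400, and none of the 18 lay above the shift (standard deviation among them 0.164). This argues against brighter hybridisation only if the same amount of these controls was added to each array. At 12 h the hybridisation controls changed by -0.335 against -0.349 (standard deviation 0.186), as dimmer hybridisation would give. The poly-A controls, which it would also lower, rose by 0.368 (standard deviation 0.274). At 0 h the poly-A controls rose by 0.887 (standard deviation 0.224), with 22 of 23 above the shift, so more labelled material is not excluded, although it would raise genes and controls alike. The amount of either kind of control added per array is not given in the sources used here. Brighter hybridisation and more labelled material at 0 h and dimmer hybridisation at 12 h therefore stay open, and no biological explanation was tested.

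ZNF zinc finger genes, many of them transcriptional repressors, were low at 44 °C against 42 °C. The pattern was found among the same 22 families written after the data were seen, so its percentiles are descriptions. The first test below was also chosen after the result was seen. Of 313 genes, 165 were at least 2-fold lower at 6 h and 119 at 12 h, with 3 and 4 higher and an excess of -0.82 and -0.37. After quantile normalization 109 and 61 were lower and 6 and 12 higher. After the median shift 99 and 44 were lower and 10 and 16 higher. After quantile normalization the percentile was 0.00 at both times, so the family lay below other genes of similar intensity on the same arrays. A uniform level difference moves the random lists alike, so this test could not have pointed to one. The counts of lower genes do depend on the scaling. Noise of dim probe sets does not account for all of it, because the 148 members with a mean of at least 4 times the floor were also at percentile 0.00. Their excess after quantile normalization was -0.76 at 6 h and -0.25 at 12 h, with 48 and 18 lower and 3 and 5 higher. Against the control the excess was 0.33 at 42 °C, 6 h and -0.54 and -0.40 at 44 °C, 6 and 12 h, so part of the gap at 6 h is a rise at 42 °C. At 42 °C, 6 h 51 members were higher and 6 lower as deposited, 27 and 5 after quantile normalization, and 19 and 10 after the median shift. The family was already low against the control at 0 h, at -0.14 at 42 °C and -0.31 at 44 °C (percentile 0.00 each). For 44 °C against 42 °C at 0 h the excess was -0.12 (percentile 0.12). The cause of the rise and of the falls was not tested.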
